A study of Caenorhabditis elegans with 4 samples.

How the data were processed

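DPY-30 ChIP-seq was carried out on mixed embryos, a mixed population of males and hermaphrodites, of the wild-type strain N2 grown at 20 °C, per the labels. Embryos were fixed in 2% formaldehyde for 30 minutes, and 2 mg of extract with 1% sarkosyl entered each immunoprecipitation, with 10% kept as input, per the labels' protocols. The labels give 2 input and 2 ChIP libraries, with replicates numbered 1 and 2. Nothing in them says whether the replicates came from separate cultures, so differences between them measure only the spread between these libraries, which may be technical. No processed files of the input libraries were analysed here, so no background could be set beside the peaks.

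The deposited files were lists of peaks with a start, an end and a score for each, in WormBase WS220 coordinates, per the file headers. BWA and the ce10 build are named for these samples, per the submitters' processing notes. Peaks were called with MACS for each ChIP library and with MACS v2 for the series-level list, per the source column of the deposited files. The deposited score is the authors' own value for a peak, and what it measures was not given in the sources used here. Nor were the control, the threshold of the calls, the read depth or whether the series-level list pooled the replicates. Scores were therefore used only within a list, to describe, rank and filter peaks and to compare X with autosomal peaks. Because a caller finds more peaks at greater depth, the numbers of peaks in different lists were not compared as amounts of binding.

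All computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and, for figures, matplotlib 3.10.9. Coordinates are printed as deposited, counted from 1. The end of the last peak over the 3 lists stood for the length of each chromosome, which only approximates it. The 2 mitochondrial peaks of the series-level list were left out of the tests. Lists were compared by overlap of at least 1 bp, tested one-sided against 1000 random placements that kept each peak's width and chromosome. Peaks per chromosome were tested with two-sided exact binomial tests against the share of length, with exact (Clopper-Pearson) 95% intervals. X and autosomal median scores were compared within a list with a two-sided permutation test of 100000 resamples, and shares with Fisher's exact test. Peaks are not replicates, so each list was tested on its own and p-values describe that list. Where Fisher's exact test set the 2 replicate lists side by side, its p-value describes the peaks of those 2 libraries only. The threshold was 0.05. Where a p-value is called adjusted, the Benjamini-Hochberg method was applied within its family of tests. All other p-values are unadjusted, among them those for ranks by score. On simulated lists, true overlaps of 30% and 60% of 882 peaks were recovered as 30.4% and 60.5%. Over 200 simulated series-level lists with no effect, the X share test called 4% and the score test 5%. The simulated peaks were independent of each other, so these rates do not cover clustering of the real peaks.

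The tests of overlap, X share, score and autosome centres, their alternatives and the rule for named peaks were fixed before the data were examined. The rule took the 12 highest-scoring peaks on X and the 12 on the autosomes among series-level peaks that overlapped a peak of both replicates, ties broken by width and then position. A peak was to be named by a gene with its start site within 500 bp. An annotation or sequence of the WS220 build was not used here, so peaks are named by position. For the same reason 3 planned results were not run, namely the share of peaks at start sites, the gene lists with a peak at the start site and the motif search on X. A gene table of the WBcel235 assembly, with 19971 nuclear protein-coding genes, served only to give the share of genes on X.

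Chosen after the data were examined were the counts among the 50 highest-scoring peaks and within other ranks, the unbroken run of X peaks, and the width of 1500 bp for broad peaks. The same holds for the tests of the other chromosomes, the comparison of X shares between the replicates, the scores of broad peaks, the comparisons of X with autosomal peaks in their overlap between lists, and the dense clusters. Alternatives planned from the start were 50% reciprocal overlap, midpoint overlap, the better-scoring 50% of a list, peaks of both replicates, merging within 1000 bp, the share of genes as the expected share, logarithms of mean scores, 25% arms and each replicate list in place of the series-level list, which also changes the caller and the score. Alternatives added later left out broad peaks, the X run or the dense clusters.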

Results

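DPY-30 binding was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mixed-stage embryos of N2, the standard wild-type laboratory strain of Caenorhabditis elegans. DPY-30 is a small subunit of the dosage compensation complex, which binds the X chromosomes of hermaphrodites and lowers their expression, and also of the COMPASS complexes, which methylate histone H3 at promoters on all chromosomes. The samples were 2 input libraries and 2 ChIP libraries made with a rabbit antibody against DPY-30. Each ChIP library had its own peak list, and a further list belonged to the series as a whole. The comparisons below are therefore between chromosomes within a list and between lists, and they ask where along the genome DPY-30 was found and whether X differed from the autosomes.

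The series-level list held 2103 peaks, of which 2101 lay on the 6 nuclear chromosomes and covered 887 kb, or 0.886% of the genome. The replicate 1 list held 882 peaks covering 584 kb, and the replicate 2 list held 817 peaks covering 579 kb. Median peak width was 260 bp in the series-level list, 420.5 bp in replicate 1 and 343 bp in replicate 2. The deposited score of a peak ran from 1.3 to 237 in the series-level list (median 5.77). In the replicate lists it started at 50.0 and had medians of 99.1 and 113.8, so scores were compared only within a list. Read depth per library was not given in the sources used here, and intervals on shares of peaks cover counting error only.

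The strongest DPY-30 peaks of the series-level list were on X. Its 31 highest-scoring peaks were all X peaks, with scores of 61.4 to 237, while the highest autosomal peak scored 60.1. These 31 peaks were narrow (459 to 1012 bp, median 716 bp) and were spread along X from position 409796 to position 17545905, with a median gap of 449 kb between neighbours. All 31 overlapped a peak in both replicates, and the midpoints of the 2 replicate peaks lay a median of 31 bp apart (largest distance, 115 bp). They made up 7.47% of the 415 X peaks. Within the replicate lists they were not the very first: their median rank was 22 of 882 in replicate 1 (lowest rank, 113) and 45 of 817 in replicate 2 (lowest rank, 216). At or above their median score stood 6 autosomal peaks in replicate 1, all 6 wider than 1500 bp, and 22 in replicate 2, of which 21 were wider than 1500 bp.

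The highest score belonged to the X peak at 14525375 to 14526294 (WS220 coordinates, as throughout), which scored 237 in the series-level list, 3063 in replicate 1 and 3100 in replicate 2. The X peaks at 2996419 to 2997430 and at 806263 to 806978 followed, both with a series-level score of 235. The X peaks at 13700451 to 13701181 and at 6296086 to 6296905 scored 234 and 233, and each reached 3100 in both replicates. The next 4 X peaks, at 8036037 to 8036907, 4208582 to 4209591, 11937032 to 11937750 and 11093776 to 11094587, had series-level scores of 232, 224, 222 and 217. The last of the 12 X peaks selected by rank were those at 9465378 to 9466150 (score 203), 17544073 to 17544870 (192) and 1626696 to 1627377 (182). Exact scores of 3100 recurred in the replicate lists, at 10 peaks of replicate 1 and 27 peaks of replicate 2, so the order of the strongest peaks within a replicate is not resolved. Genes at these positions were not named, because an annotation of the WS220 build was not used here.

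**Figure D1:**
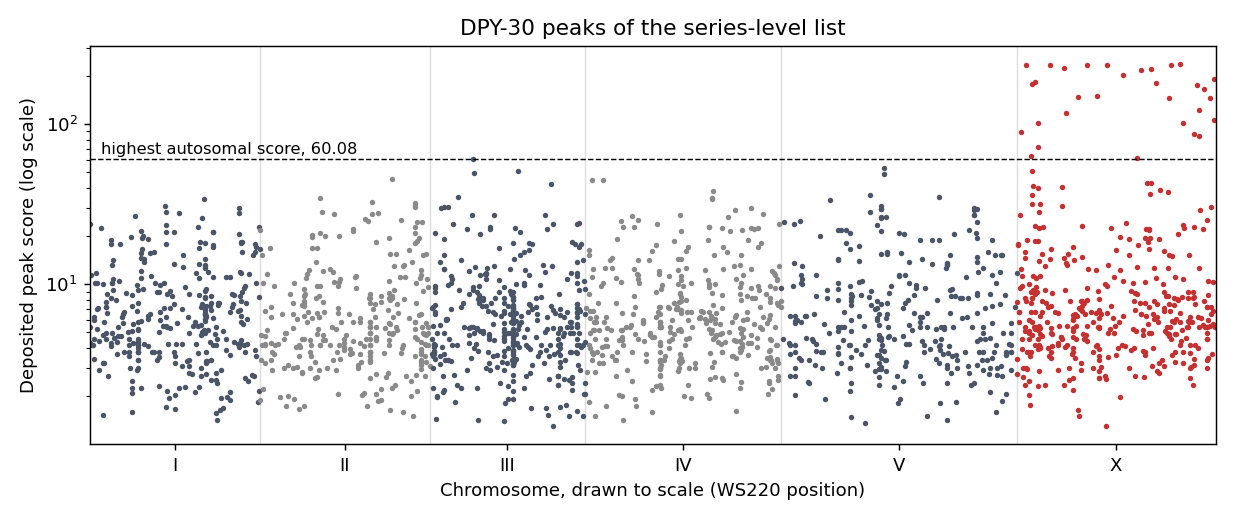
Deposited score (log axis) of each nuclear peak of the series-level list against its WS220 position, chromosomes drawn to scale, with X in red. The dashed line marks the highest autosomal score, 60.1, and the 31 points above it are all on X.

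The share of X peaks fell steeply with rank. Among the 50 highest-scoring series-level peaks, 40 were on X (80%, exact 95% interval 66.3 to 89.97%), whereas X made up 17.7% of the genome length (exact binomial p = 1.21e-21). At ranks 51 to 100 the X share was 16%, and over ranks 401 to 2101 it was 18.2% (16.4 to 20.1%). In replicate 1, 31 of the 50 highest-scoring peaks were on X (62%, exact binomial p = 4.01e-12), and ranks 101 to 200 also held more X peaks than the length share (30%, exact binomial p = 0.00235). In replicate 2 the count was 25 of 50 (50%, exact binomial p = 1.87e-07). With peaks wider than 1500 bp left out, an alternative chosen after seeing the data, X held 40, 36 and 27 of the first 50 ranks in the series-level, replicate 1 and replicate 2 lists. As the lists differ in length, the same ranks cover different fractions of each, and these counts were not tested as a change between lists.

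**Figure D2:**
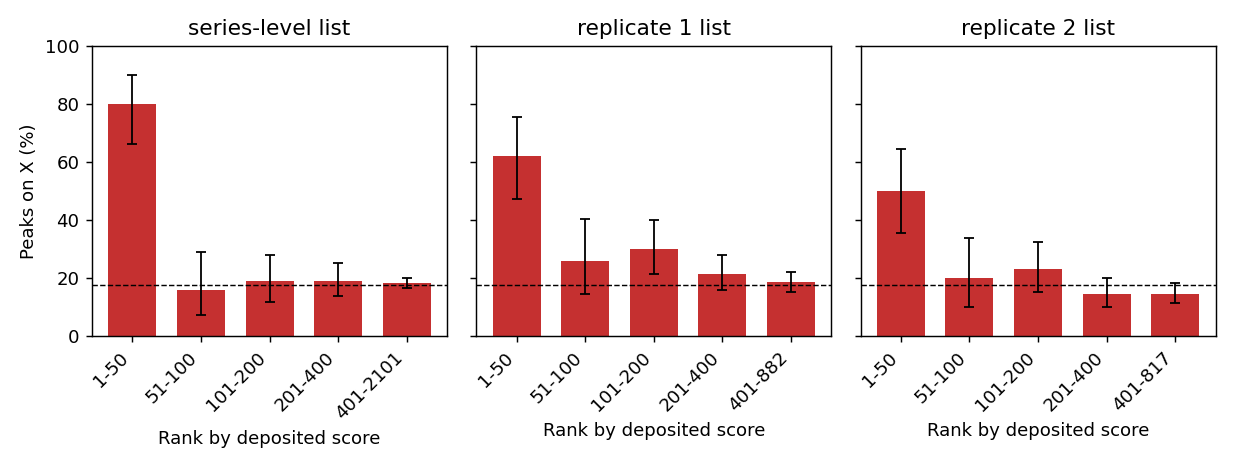
Share of peaks on X (percent, bars) by rank of the deposited score in each of the 3 lists, with exact 95% binomial intervals. The dashed line is the X share of genome length, 17.7%; the first 50 ranks stand at 80%, 62% and 50%.

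The median X peak also scored above the median autosomal peak in each list. In the series-level list the median score was 6.49 on X (interquartile range 4.52 to 12.2) and 5.48 on the autosomes (3.75 to 9.42), a difference of 1.01 (two-sided permutation test, p = 0.00056, Benjamini-Hochberg adjusted p = 0.00056 over 3 lists). The medians were 143 and 92.0 in replicate 1 (permutation adjusted p = 3e-05, from the smallest p that the permutations can give) and 183 and 108 in replicate 2 (permutation adjusted p = 0.00051). The size of the series-level difference depended on the peaks compared. Among the 380 peaks found in both replicates, whose 96 X peaks include all of the 31 strongest, it was 7.96 (permutation p = 1e-05, the smallest possible). In the better-scoring 50% of the list, a cut on the score that can itself narrow the difference, it was 0.38 (permutation p = 0.439). Without the 31 strongest peaks, whose removal lowers the X median by construction, it was 0.56 (permutation p = 0.0504).

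The 12 highest-ranked autosomal peaks found in both replicates scored 35.1 to 60.1 in the series-level list. Of these, 4 lay on III, 4 on V, 3 on IV and 1 on II. The III peak at 3867310 to 3867711 (402 bp) scored 60.1, with 273 in replicate 1 and 349 in replicate 2. The III peak at 7854389 to 7854813 scored 50.8 and the III peak at 10758945 to 10759330 scored 42.3. The III peak at 3897102 to 3897755 had a series-level score of 49.3. Its score was 87.8 in replicate 1, below that list's median of 99.1, and 1562 in replicate 2, above that list's median of 113.8. A pair of neighbouring broad peaks on V, at 9086757 to 9088759 and 9088869 to 9091113, scored 53.2 and 48.6. Chromosome IV contributed the peaks at 654730 to 655104 (44.9), 1659043 to 1659530 (44.6) and 11400310 to 11401401 (38.2), and chromosome II the broad peak at 11758488 to 11760339 (45.5). The remaining V peaks were those at 14038484 to 14038987 (35.1) and at 7916846 to 7925033 (36.2), the latter 8188 bp wide and scoring 132 in replicate 1 and 3100 in replicate 2.

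By number, peaks were spread over all chromosomes, with V the sparsest in the series-level list. V carried 15.4 peaks per Mb, 0.736 times its share of length (exact binomial, adjusted p = 2.36e-09 over 18 tests of chromosomes and lists). X carried 23.5 peaks per Mb and held 415 of 2101 peaks (19.8%, 18.1 to 21.5%), 1.12 times its share of length (exact binomial p = 0.0139, adjusted p = 0.0416). Without the 31 strongest peaks, whose removal lowers it by construction, the X ratio was 1.05 (exact binomial p = 0.3). Chromosome III carried the most, 27.2 per Mb or 1.30 times its share (exact binomial adjusted p = 1.5e-06). Chromosomes I, II and IV, at 21.4, 19.6 and 21.1 peaks per Mb, did not pass the threshold. The binomial test takes peaks as independent of their neighbours, which the clusters described further on show they were not.

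The replicates differed in these shares. X held 206 of 882 peaks in replicate 1 (23.4%, 20.6 to 26.3%, ratio 1.32, exact binomial adjusted p = 0.000129) and 148 of 817 in replicate 2 (18.1%, 15.5 to 20.9%, ratio 1.03, exact binomial adjusted p = 0.842). The mean X share of the replicates was 20.7% ± 3.71 (SD, n = 2), and the difference between them was itself past the threshold (Fisher's exact p = 0.0085, adjusted p = 0.0136 over 7 comparisons). This test takes the lists as independent, although 417 of the 882 replicate 1 peaks overlapped a replicate 2 peak. Its p-value therefore describes the peaks of these 2 libraries only. Without the dense clusters described next the X shares were 23.8% and 20.9%, and their difference did not pass (Fisher's exact p = 0.175). That removal took 136 replicate 2 peaks, 6 of them on X, and 34 replicate 1 peaks, 4 of them on X. It thus narrows the difference by construction. The excess on III was present in replicate 2 (ratio 1.33, exact binomial adjusted p = 0.00112) and not past the threshold in replicate 1 (1.07, exact binomial adjusted p = 0.562). V was low in replicate 2 (0.791, exact binomial adjusted p = 0.00692), and in replicate 1 its ratio of 0.884 did not pass (exact binomial adjusted p = 0.164).

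Part of the autosomal peaks lay in dense clusters. Defined after seeing the data as at least 10 peaks of a list with gaps of at most 5000 bp, clusters formed 11 regions of 8.38 to 46.5 kb, 4 of them on III, 2 each on I and X and 1 each on II, IV and V. The widest, at 7405312 to 7451785 on III, held 49 series-level peaks, 33 peaks of replicate 2 and 9 of replicate 1. The regions at 9808297 to 9825239 on II and 6711592 to 6729499 on IV held 25 and 18 peaks of replicate 2 and 0 of replicate 1. At 13068098 to 13086564 on III the counts were 17 in replicate 2 and 2 in replicate 1, and at 17384100 to 17394544 on V they were 16 and 5. The region at 10204147 to 10219060 on I differed from these, with 8 peaks in replicate 1 and 6 in replicate 2. By list, 11 clusters formed in the series-level list, 5 in replicate 2 and 0 in replicate 1. The 11 regions held 194 series-level peaks (9.23%), 136 peaks of replicate 2 (16.6%) and 34 of replicate 1 (3.85%). Random placements of the peaks within their chromosomes gave at most 8 series-level peaks in such a run (one-sided permutation p = 0.001, the smallest that 1000 placements can give).

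**Figure D3:**
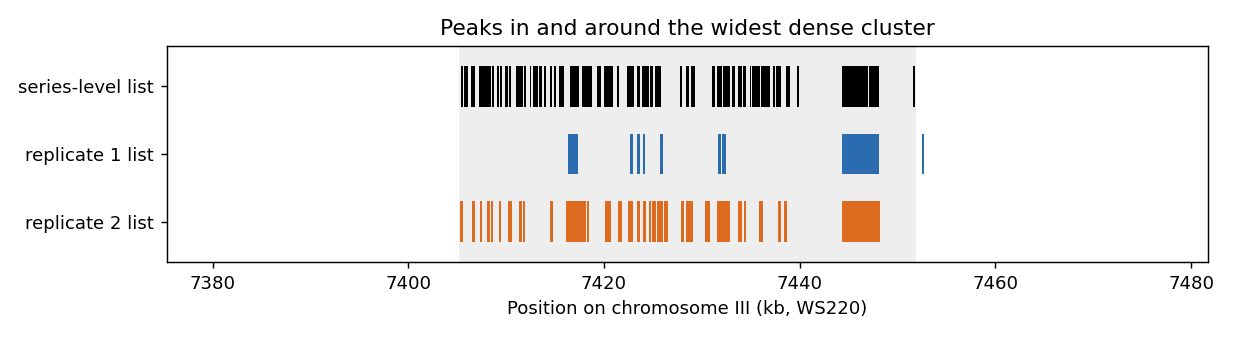
Peaks of the 3 lists (bars, drawn to scale) in and around the cluster at 7405312 to 7451785 on chromosome III, shaded, against WS220 position in kb. The cluster holds 49 series-level peaks, 9 of replicate 1 and 33 of replicate 2, and few peaks lie in its flanks.

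With the dense clusters left out, the excess on III was lost and the X ratios were higher. Some of this follows by construction, since 88 of the 194 series-level peaks removed were on III and 21 on X. The III ratio was 1.09 in the series-level list (exact binomial adjusted p = 0.221) and 0.992 in replicate 2 (exact binomial adjusted p = 1). The X ratio was 1.17 in the series-level list (exact binomial adjusted p = 0.00462) and 1.35 in replicate 1 (exact binomial adjusted p = 5.71e-05). In replicate 2 it was 1.18, with 142 of 681 peaks on X, and did not pass after adjustment (exact binomial p = 0.0347, adjusted p = 0.104). V stayed low in the series-level list at 0.785 times its share of length (exact binomial adjusted p = 1.45e-05), while in replicate 2 its ratio of 0.836 no longer passed (exact binomial adjusted p = 0.0964).

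**Figure D4:**
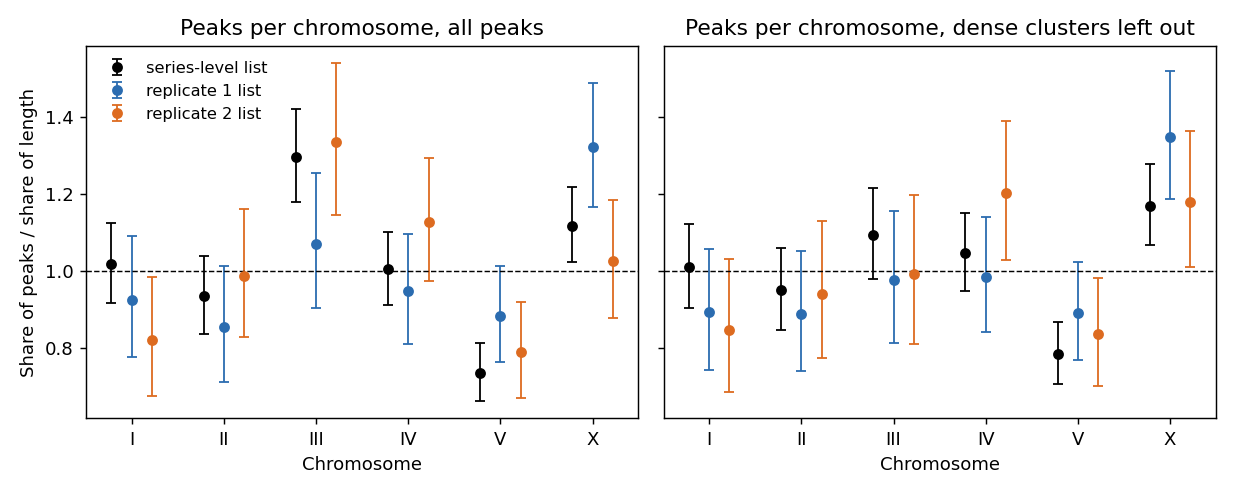
Share of peaks divided by share of genome length for each chromosome in the 3 lists, with exact 95% binomial intervals, for all peaks (left) and with the dense clusters left out (right). The series-level ratio of III goes from 1.30 to 1.09 and that of X from 1.12 to 1.17.

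The replicates shared close to 50% of their peaks. Of the 882 peaks of replicate 1, 417 (47.3%) overlapped a replicate 2 peak by at least 1 bp, and 378 of the 817 peaks of replicate 2 (46.3%) overlapped a replicate 1 peak. Random placements within chromosomes gave means of 1.01% and 1.12% (one-sided permutation p = 0.001 for both, the smallest possible). X peaks of replicate 2 were found in replicate 1 more often than its autosomal peaks, 94 of 148 (63.5%) against 284 of 669 (42.5%; Fisher's exact adjusted p = 2.66e-05 over 6 tests). Outside the 31 strongest peaks the X share was 53.8% (Fisher's exact p = 0.0262), although this removal lowers it by construction. For replicate 1 peaks the shares were 49.0% on X and 46.7% on the autosomes (Fisher's exact adjusted p = 0.578).

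The series-level list contained most of the replicate peaks and many others. It overlapped 754 of the replicate 1 peaks (85.5%) and 677 of the replicate 2 peaks (82.9%). Of its own 2101 peaks, 380 (18.1%) overlapped a peak of both replicates, 372 of replicate 1 alone, 317 of replicate 2 alone and 1032 (49.1%) of neither. The 380 peaks found in both were the stronger and wider ones, with a median score of 17.8 and a median width of 603 bp, against 4.48 and 202 bp for the peaks found in neither. X held 96 of the 380 (25.3%, 20.97 to 29.9%), and 23.1% of X peaks were found in both replicates against 16.8% of autosomal peaks (Fisher's exact p = 0.0035). Without the 31 strongest peaks, all of them found in both, 65 of the 384 other X peaks (16.9%) were found in both (Fisher's exact p = 1). This removal lowers the X share by construction, since no autosomal peaks were taken out.

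Broad peaks, wider than 1500 bp, lay on all chromosomes, and X did not stand out among them. The series-level list had 70, which held 24.3% of all bases covered, and 62 of them overlapped a peak in both replicates. They were distributed as 13 on I, 7 on II, 13 on III, 11 on IV, 15 on V and 11 on X (X share 15.7%, 8.11 to 26.4%, exact binomial p = 0.756). The widest spanned 11097 bp at 15060243 to 15071339 on I, toward the right end where the ribosomal RNA gene array lies, and scored 22.8 in the series-level list, 1962 in replicate 1 and 3100 in replicate 2. Others were the X peak at 10361257 to 10369190 (7934 bp, score 5.28) and the V peaks at 10605625 to 10612500 (6876 bp, 15.8), 17119928 to 17126584 (6657 bp, 27.2) and 3434572 to 3441104 (6533 bp, 20.1). Broad peaks scored above narrower ones in every list, with median scores of 19.9 against 5.52 in the series-level list, 609 against 94.6 in replicate 1 and 1323 against 103 in replicate 2. The median broad peak stood at the top 8.95%, 9.01% and 8.45% of these lists by score.

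**Figure D5:**
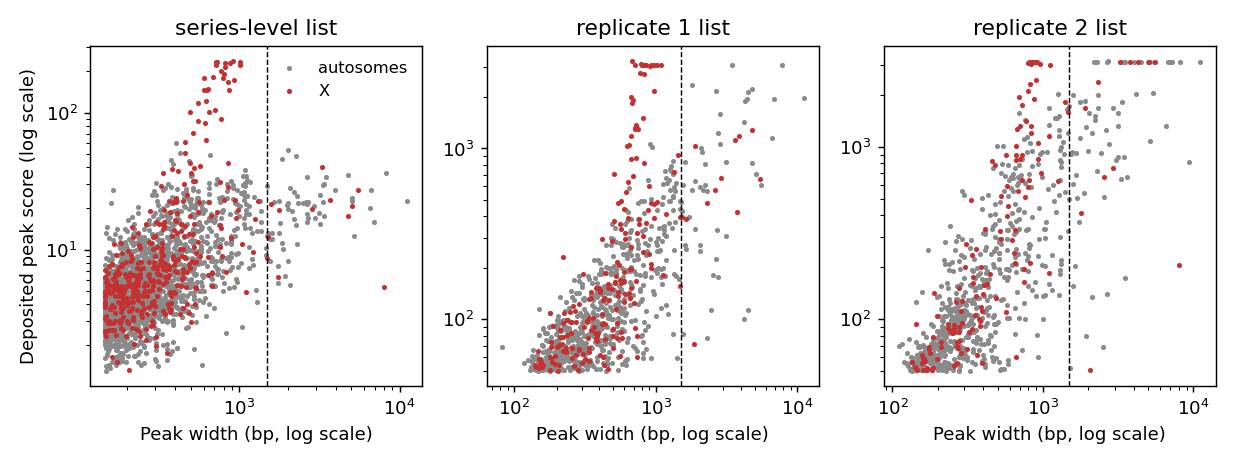
Deposited score against peak width (both log axes) for each nuclear peak of the 3 lists, X in red and autosomes in grey, with a dashed line at 1500 bp. The strongest series-level peaks are X peaks of 459 to 1012 bp, while in both replicate lists peaks wider than 1500 bp also reach scores of 3100.

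Along the autosomes, any central excess of peaks was small and depended on how it was measured. The central 33.3% of each autosome held 602 of 1686 series-level peaks (35.7%, 33.4 to 38.05%), which did not pass after adjustment (exact binomial p = 0.0412, adjusted p = 0.124 over 3 lists). The shares in replicates 1 and 2 were 35.7% (exact binomial adjusted p = 0.309) and 34.5% (exact binomial adjusted p = 0.512). With the outer 25% at each end taken as arms, the centres held 53.3% of series-level peaks against 50% of length (exact binomial p = 0.00792), and in the better-scoring 50% of peaks the central 33.3% held 36.9% (exact binomial p = 0.0339), both unadjusted. With the dense clusters left out the series-level share was 32.8% (exact binomial p = 0.703).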

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

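Leaving out broad peaks, the run of 31 X peaks or the dense clusters, and all alternatives for the first 50 ranks, for single chromosomes and for comparisons of X shares, were chosen after the results were seen. Of 48 alternatives, 35 left a result in its direction and on its side of the threshold, or a count within 1.5 times. Replicate overlap stayed at 33.8 to 65.3% for replicate 1 and 36.5 to 64.8% for replicate 2. A replicate was left out by putting the list of the other in place of the series-level list, which also changes the caller and the score, so these shifts cannot be put down to the replicate. The X ratio of peak numbers was then 1.03 in the replicate 2 list (exact binomial p = 0.748) and 1.32 in the replicate 1 list. It was 1.05 without the X run (exact binomial p = 0.3), which removes X peaks by construction. Its other alternatives gave 1.13 to 1.44, all past the threshold. The score difference of 1.01 was 7.96 among peaks of both replicates (permutation p = 1e-05), 0.38 in the better-scoring 50% (permutation p = 0.439) and 0.56 without the X run, which lowers it by construction. The cause of the first of these shifts and of the second was not tested, though a cut on the score can itself narrow the difference in the second. X peaks among the first 50 ranks numbered 25 in the replicate 2 list and 31 in the replicate 1 list. The central share of autosomal peaks passed an unadjusted test with 25% arms (53.3% against 50%, exact binomial p = 0.00792) and in the better-scoring 50% (36.9%, exact binomial p = 0.0339). It was 34.5% in the replicate 2 list and 35.7% in the replicate 1 list, neither past the threshold. Without the dense clusters, a removal that lowers III and raises X by construction, it was 32.8%, below the share of length, the III ratio was 1.09 in the series-level list and 0.992 in replicate 2, the V ratio in replicate 2 was 0.836, and the X share of replicate 1 was above that of replicate 2 by 2.97 percentage points, none past the threshold. Removing the dense clusters takes mostly autosomal peaks of replicate 2, so it also narrows the difference between the replicates by construction. Without the X run, a removal that lowers the X share by construction, the X and autosomal shares of peaks found in both replicates differed by 0.0825 percentage points. Leaving out a replicate gives no overlap value. The alternatives for start sites, gene lists and the motif were not run, as those results were not. No paired analysis was possible because no values of the input libraries were analysed here. With 2 ChIP libraries and no read depth, differences in sequencing depth between the replicates could not be assessed.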

Other observations

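The tests of chromosome parts, of 1-Mb windows, of chromosome ends and of unshared peaks were all chosen after the peak lists were seen, and so were the tests of width, of a single replicate, of raised coverage of X and of broad peaks. X was less occupied in its middle. Its central 33.3% held 106 of 415 series-level peaks (25.5%, 21.4 to 30.0%; exact binomial adjusted p = 0.00417 over 6 chromosomes), with 170 peaks to the left and 139 to the right. The central share of X was 24.8% in replicate 1 (exact binomial p = 0.00951) and 24.3% in replicate 2 (exact binomial p = 0.023), both unadjusted. Among the 96 series-level X peaks found in both replicates it was 24.0%, not past the threshold (exact binomial p = 0.0518). For the 31 strongest peaks, 6 were central (exact binomial p = 0.127). Without the dense clusters the central share of X was 24.1% (exact binomial adjusted p = 0.000443), while III and IV went from 41.1% and 39.02% to 32.1% and 35.5%, no longer past the threshold. The fullest 1-Mb window of X, from 1 to 2 Mb, held 51 series-level peaks against a median window of 24 and at most 45 in random placements (one-sided permutation adjusted p = 0.002). It included 5 of the 31 strongest peaks, 18 peaks found in both replicates, 27 replicate 1 peaks and 22 replicate 2 peaks, and none of the dense clusters. Crowded windows were not particular to X: the fullest windows of I, III, IV and V also passed, with 69 peaks from 7 to 8 Mb on III (permutation adjusted p = 0.002). Without the dense clusters, those of X (permutation adjusted p = 0.006), of V with 32 peaks from 8 to 9 Mb (permutation adjusted p = 0.006) and of II with 32 from 14 to 15 Mb (permutation adjusted p = 0.036) passed.

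Both replicates had a peak at the left end of each of the 6 nuclear chromosomes, where the telomeric repeats lie, starting within the first 3 bases. Right ends were not examined. Repeats collapsed in the assembly cannot be told apart from binding here, as the input signal was not analysed. These were 210 to 525 bp wide in replicate 1 and 221 to 492 bp wide in replicate 2. The end of I scored highest in both, 285 in replicate 1 and 1010 in replicate 2, followed by the end of X with 134 and 489. In the series-level list such end peaks were present on 3 chromosomes, I (score 23.6), V (9.43) and X (7.73), and on II a peak with a score of 21.8 started at base 88. The mitochondrial genome carried 2 series-level peaks, at 5935 to 6195 (score 2.76) and 8695 to 8917 (2.63), and no replicate peak.

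The concentration of the strongest peaks on X was weighed against 3 technical explanations. Broad regions of repeated sequence are argued against by the widest of the 31 peaks, at 1012 bp. Width does not bear on short stretches of sequence present in many copies, and the input signal over the peaks was not analysed here. A signal of a single replicate is excluded, since 31 of the 31 peaks overlapped a peak in both. In the series-level list, raised coverage of X as a whole is argued against as the whole cause. Below the first 50 ranks of that list X held 18.3% of peaks (exact 95% interval 16.6 to 20.03%), near its 17.7% of length. Leaving out those 50 ranks, 40 of them X peaks, lowers this share by construction. A small rise is not excluded. In replicate 1, X held 30% of ranks 101 to 200 (exact binomial p = 0.00235) and 18.5% of ranks 401 to 882 (15.1 to 22.2%). In replicate 2, X held 23% of ranks 101 to 200 (exact binomial p = 0.188). A rise of X beyond the first 50 ranks is therefore not excluded for replicate 1. The design has no mutant and no second antibody, so no biological explanation was tested; binding at a limited set of strong sites on X, as is known for the dosage compensation complex, stays a hypothesis.

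Broad peaks scored above narrower peaks in all 3 lists, and most of the series-level ones overlapped a peak of both replicates. An overlap of at least 1 bp is easily met by a wide peak and does not show that both replicates were broad there. The X share of the broad series-level peaks, 15.7% (8.11 to 26.4%), argues only against a concentration on X like the 80% among the 50 highest-scoring peaks. A smaller X excess is not excluded, since the interval includes the 19.8% of the whole list. Sequence collapsed in the assembly or present in many copies cannot be told apart from broad binding: 62 of the 70 overlapped a peak in both replicates, which either would give, and the input signal that would decide was not analysed here. No biological explanation was tested.

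Peaks found in replicate 1 alone lay on X more often (105 of 465, 22.6%) than peaks found in replicate 2 alone (54 of 439, 12.3%; Fisher's exact p = 5.37e-05, adjusted p = 0.000154). Broad peaks or low-scoring peaks as the whole cause are argued against, since the difference held without broad peaks (Fisher's exact p = 6.5e-05) and in the better-scoring 50% (26.2% against 11.4%, Fisher's exact p = 6.61e-05). The dense clusters, which are mostly in replicate 2 and on autosomes, could account for part of it. Without them the shares were 22.1% and 14.7% and still differed (Fisher's exact p = 0.00969). As no cluster formed in the replicate 1 list, this removal narrows the difference by construction, so how large a part was not settled. Additional copies of these segments in a library, for example from cloned or amplified DNA, could raise a whole segment over many kb, but neither this nor dense binding was tested, as read coverage and input signal were not analysed here. No biological explanation was tested, because both libraries belong to the same group.

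Whether weaker X peaks lie near the strongest ones, as spreading from strong sites would give, was tested as a hypothesis by shifting the 31 peaks along X. The 384 other series-level X peaks lay a median of 154 kb from the nearest of the 31, against 179 kb in the shifts (149 to 211 kb; one-sided permutation p = 0.0531, adjusted p = 0.0708 over 4 tests). In replicate 1 the distance was 133 kb (permutation p = 0.0117, adjusted p = 0.0468) and in replicate 2 it was 149 kb (permutation p = 0.18). The hypothesis stays open: the series-level distance lies inside the central 95% of shifts but near its lower bound, replicate 1 alone passed, and a p that misses the threshold does not show that there is no such relation. An even layout of the 31 peaks along X was tested by the coefficient of variation of their gaps, 0.72 against a median of 0.935 for random positions (0.692 to 1.31; one-sided permutation p = 0.0441, adjusted p = 0.0708). It stays open as well, since the one-sided test passed before adjustment and not after it, although the value lies inside the central 95% of random positions.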
